A study of Mus musculus with 12 samples.

How the data were processed

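The series holds 12 Affymetrix mouse arrays, 6 of PC1 high and 6 of PC1 low B1a cells from C57BL/6 mice. Per the labels' protocols, cells were sorted by flow cytometry, their RNA was extracted and amplified with NuGEN Ribo-SPIA, and double-stranded cDNA was fragmented, end-labelled with biotin and hybridised. The deposited values are log2 signals, which the authors made with GCOS 1.4 and RMA, per the submitters' processing notes. RMA corrects the background, normalises between arrays and summarises the probes of each probe set. The RMA software, the array annotation and any later step are not given in the sources used here. The values lay between 2.66 and 13.5, as log2 values do, and the array medians between 7.78 and 7.88, so the arrays share a level but not an identical distribution. Scanner intensities were not used here. No 2 arrays held the same values. Groups were taken from the sample labels. Per the series' design text each preparation came from an individual mouse; whether the PC1 high and PC1 low preparations of equal number share a mouse is not stated, and p values measure the spread between these preparations.

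The table holds 35557 probe sets. GEO's platform annotation paired 21789 of them with 1 gene and 1621 with several genes, and left 12147 unnamed. Gene identifiers of 21698 probe sets with 1 gene were found in a RefSeq gene table of assembly GRCm38.p6, which changed no symbol, served for names and for which genes overlap, and gave no coordinates; the other 91 kept the annotation's symbol. Probe sets with several genes or none were left out of the gene-level tests. For each gene, the probe set with the highest mean over the 12 arrays stood for it, which gave 19938 genes, 999 of them with more than 1 probe set. Called genes with several probe sets (Ahnak2, Dennd4a, Igha and Pgap1) had the same direction on all of them. Control probe sets are not marked in the tables used here, so the alternatives that leave them out used the 23410 annotated probe sets. Enpp1 and Cd19 were not analysed here because the annotation names neither.

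Differences were tested with limma 3.58.1 in R 4.3.3 on the deposited log2 values (lmFit and eBayes, two-sided, PC1 high minus PC1 low, 6 arrays per group, no covariates), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Errors are limma's standard errors or SDs of the group, as stated, and intervals are limma's 95% intervals. Gene lists were tested with limma's camera, two-sided, with a preset correlation of 0.01 between genes and adjustment over the lists tested. Camera was repeated with a correlation estimated from the data, and fry, which asks whether a list's genes move 1 way on balance without comparing them with other genes, was run as well. Under the estimated correlation 3 of the 9 calls held, those of the immunoglobulin constant region, immunoglobulin light chain variable and follicular B-2 lists. Under fry 2 held, those of the constant region and follicular B-2 lists. Members were also counted after adjustment over the list alone.

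Designs, alternatives, gene lists and the rule for the genes named were fixed before the data were examined, except where stated. The rule took the sort markers, then of the genes past the threshold up to 12 with the largest difference in each direction, passing over clone names and immunoglobulin variable segments, and up to 4 members of each list described, called members first and otherwise those with the smallest p. It named 12 higher and 8 lower genes. Igkv4-91, Igkv6-20, Tsga10, Eps8 and E030011O05Rik also passed the threshold and were named after their values were seen, as were members that passed over a list alone beyond the first 4, Igf2r and the genes described among the other observations.

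Of the 34 gene lists, 32 had at least 3 measured members and were tested. They covered B-1, follicular B-2 and marginal zone B cell genes, plasma cell differentiation, the unfolded protein response, B cell identity transcription factors, B cell receptor signalling, fetal lymphopoiesis, cell cycle, regulatory B cell molecules, extracellular nucleotide metabolism, homing receptors, innate sensing, NF-kB targets, immediate early genes, MHC class II, interferon-stimulated genes, cell survival, cytokines, glycolysis, lipid metabolism, class switching, immunoglobulin constant region and light chain variable genes, and markers of T cells, macrophages, NK cells, neutrophils, mast cells, dendritic cells, erythroid cells and platelets, and mesothelial and stromal cells. The list of sort markers had 2 measured members and that of heavy chain variable genes 0, and neither was tested. The median, the mean and camera's direction differed in sign for the MHC class II, homing, macrophage, NF-kB, NK cell, cell survival and cytokine lists, none of which was called.

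The procedure was tested on simulated data for the PC1 high and PC1 low comparison, with 19938 genes of which 200 were changed by known amounts. It recovered 90% of genes changed by 0.5 log2 units, 100% by 1, 98% by 1.5 and 100% by 2 (50 genes each). Of 204 calls 10 were false. With 200 changed genes the adjusted threshold was easier to pass than on the real arrays, where 25 genes passed. The shares recovered thus do not carry over. On the real arrays Trps1 (-1.12, limma adjusted p = 0.0848) and Cd300lf (0.88, limma adjusted p = 0.0635) did not pass. With no gene changed, 1 of 20 simulations made any call. In a separate simulation of 32 lists with 1 list shifted by 0.3, 0 unshifted lists were called. Simulated genes were drawn independently of each other, so this cannot show how camera treats lists whose genes move together.

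Alternatives were the mean of a gene's probe sets, every annotated probe set tested by itself, dim genes left out, a trended and a robust variance prior, array weights, the replicate number as a block, arrays centred on their medians, quantile normalization, each array left out in turn, stricter thresholds, an estimated correlation and fry. Chosen after the data were seen were leaving out the 2 arrays that stand apart, the Xist level of each array as a covariate, and a fit over every probe set of the table. A robust prior cannot be used in camera, and the alternatives for Enpp1 gave no value.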

Results

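Gene expression was profiled in B1a cells of C57BL/6 mice, a B lymphocyte subset that makes natural antibodies. The cells had been sorted by flow cytometry as CD19-positive, CD5-positive and CD23-negative and then divided by their surface level of PC1, the nucleotide-hydrolysing ectoenzyme encoded by Enpp1. There were 6 preparations of PC1 high cells and 6 of PC1 low cells, each hybridised to its own Affymetrix array after amplification of the RNA. The labels describe each preparation as coming from an individual mouse. They name both the spleen and the peritoneal cavity as the source of the cells, so the tissue is left open here. Values were log2 RMA signals, with array medians between 7.78 and 7.88, and the number of arrays limits the precision of what follows.

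The comparison asked how B1a cells with much PC1 on their surface differ from those with little. PC1 high cells had far more RNA of Igkv4-91, a kappa light chain segment known from B-1 cell antibodies to phosphatidylcholine, than PC1 low cells, by 8.08 times (log2 difference 3.01, SE 0.27, n = 6 per group). In the opposite direction, the probe set used for Igha, the IgA heavy chain constant region, read 2.97 times higher in PC1 low cells (log2 difference -1.57, SE 0.12, n = 6 per group). Ifi207, an interferon-inducible protein of the nucleic acid sensing PYHIN family, and Cd63, a tetraspanin of late endosomes and lysosomes, were higher in PC1 high cells by 4.48 times and 3.88 times. Genes typical of follicular B-2 cells, among them Cr2, Fcrl1 and Fcer2a, were lower in PC1 high cells.

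Of 19938 genes tested with limma, 25 differed at a Benjamini-Hochberg adjusted p under 0.05, 16 of them higher and 9 lower in PC1 high cells. In 24 of the 25, all but Airn, the values of the 2 groups did not overlap; over all genes the groups did not overlap for 92, or 0.461%, where chance gives 0.216%. The 2 smallest adjusted p values were those of Igha (2.14e-05) and Igkv4-91 (0.000111). Without PC1 high replicate 2, 3 or 5 or PC1 low replicate 1, the number of higher genes became 10, 7, 30 and 7, respectively. With arrays weighted by their quality, limma called 49 higher and 32 lower genes, the 25 included, and with each array centred on its median it called 8 and 5.

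**Figure D1:**
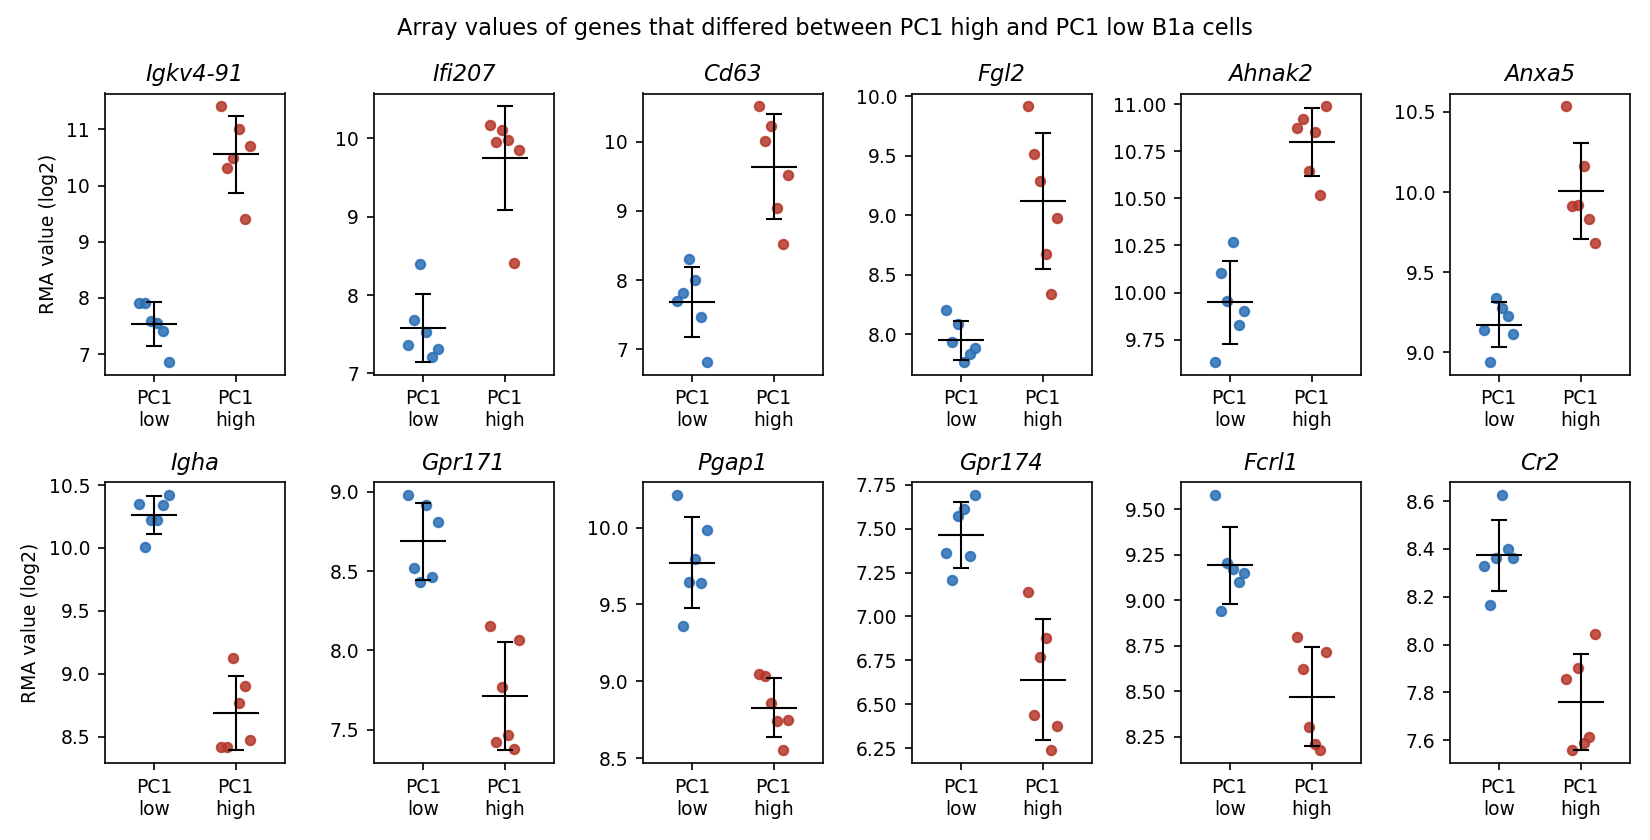
Log2 RMA values of 12 genes on each array, with PC1 low arrays in blue and PC1 high arrays in red (n = 6 per group); each point is an array, and the bars show the group mean and SD. The upper panels show genes that were higher in PC1 high cells and the lower panels genes that were lower, and in none of the 12 do the groups overlap; each panel has its own axis range.

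Fgl2, a fibrinogen-like protein with a secreted immunosuppressive form, was higher by 1.17 log2 units (SE 0.20, limma adjusted p = 0.0353). The calcium-dependent phospholipid-binding proteins Anxa5 and Anxa2 were higher by 0.84 (SE 0.12) and 0.69 (SE 0.12), and the large scaffold protein Ahnak2 by 0.85 (SE 0.10). Smaller differences were found for Sft2d2 (0.59), Asph, an aspartate hydroxylase of the endoplasmic reticulum (0.54), Gas7 (0.51), Etl4 (0.51), the Wnt receptor Fzd6 (0.50), Tsga10 (0.46), the actin regulator Eps8 (0.45) and the unnamed clone E030011O05Rik (0.33). Airn, the long noncoding RNA that overlaps Igf2r on the opposite strand, was higher by 0.68 (SE 0.12). Double-stranded cDNA was labelled, so the strand of the Airn signal was not determined; Igf2r itself read 0.33 higher and did not pass (limma adjusted p = 0.126). Ifi207 had a mean of 9.74 ± 0.66 (SD, n = 6) in PC1 high and 7.58 ± 0.44 in PC1 low cells, with PC1 high replicate 5 at 8.41 and the other PC1 high arrays between 9.85 and 10.16.

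Among the genes that were lower in PC1 high cells, 3 code for B cell surface receptors and 2 for orphan or lipid-sensing G protein-coupled receptors. The complement receptor Cr2 (CD21) was lower by a log2 difference of -0.61 (SE 0.09, limma adjusted p = 0.0150), Fcrl1, an Fc receptor-like protein of B cells, by -0.72 (SE 0.12) and Fcer2a by -0.48 (SE 0.07). Gpr171 differed by -0.98 (SE 0.15) and Gpr174, a lysophosphatidylserine receptor of lymphocytes, by -0.83 (SE 0.14). Pgap1, which remodels glycosylphosphatidylinositol anchors, differed by -0.94 (SE 0.12), and Dennd4a, an exchange factor for Rab GTPases, by -0.58 (SE 0.09).

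Of the 4 genes of the sort markers, 2 were measured. Cd5, the marker that both gates shared, averaged 8.53 ± 0.19 (SD, n = 6) in PC1 high and 8.51 ± 0.06 in PC1 low cells, a log2 difference of 0.02 (95% interval -0.15 to 0.19). Fcer2a codes for CD23, which both gates excluded, and averaged 7.16 ± 0.12 in PC1 high and 7.64 ± 0.12 in PC1 low cells. Enpp1, the gene of the sorted protein, and Cd19 were not analysed here, because the annotation used here names neither.

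Most immunoglobulin genes other than Igkv4-91 read lower in PC1 high cells. The list of constant region genes, which also counts the joining chain gene Jchain, was lower as a list of 4 measured members (median log2 difference -0.53, adjusted p = 2.14e-09 by limma's camera, and 0.00215 with an estimated correlation). Of them Igha was lower when adjusted over all genes, and Igha, Ighm and Ighg3 when adjusted over the list alone. Ighm differed by -0.63 (SE 0.12, limma adjusted p = 0.0752 over all genes) and Ighg3 by -0.44 (SE 0.18). Jchain, whose protein joins secreted IgM and IgA, did not differ (-0.02, SE 0.10). Ighg3 averaged 5.59 in PC1 high and 6.04 in PC1 low cells, with PC1 low replicate 6 highest at 6.93. Jchain averaged 6.38 and 6.41. Olfactory and vomeronasal receptor genes, which B cells are not known to use, had array medians of 6.27 to 6.54. Igha and Ighm thus were the members read well above that level. A second probe set of Igha gave -1.68, and 2 other probe sets of Ighm gave -0.37 (SE 0.06) and -1.19 (SE 0.26). Some further probe sets list Igha together with heavy chain variable segments. Whether those named Igha or Ighm alone read only the constant region was not tested.

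The 8 light chain variable segments named alone moved in opposite directions. Igkv4-91 was higher, and the other 7 had values below 0, with Igkv6-20 lower when adjusted over all genes (log2 difference -0.57, limma adjusted p = 0.0482). Adjusted over the list alone, 5 segments were lower, among them Igkv6-20, Igkv10-96 (-0.58), Igkv19-93 (-0.65) and Igkv8-30 (-0.50). A second probe set of Igkv19-93 gave -0.08 (SE 0.07). Igkv8-30 averaged 5.65 in PC1 high and 6.16 in PC1 low cells, below the olfactory and vomeronasal receptor medians of 6.27 to 6.54. The list's median was -0.49 and its mean -0.04, since Igkv4-91 balances the rest, and camera placed it lower (adjusted p = 3.21e-05, and 0.0260 with an estimated correlation). That call ended when dim genes were left out (adjusted p = 0.189). Probe sets that match several Ig segments or constant regions at once were lower in PC1 high cells in 14 of 16 cases, 3 of them past the threshold. Those shared among other Igkv4 segments, most of which also list the kappa constant gene Igkc, lay between -0.11 and 0.21. The shared kappa probe sets that fell furthest gave -2.76, -1.71 and -1.51, and of these only the one at -1.71 passed the threshold.

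**Figure D2:**
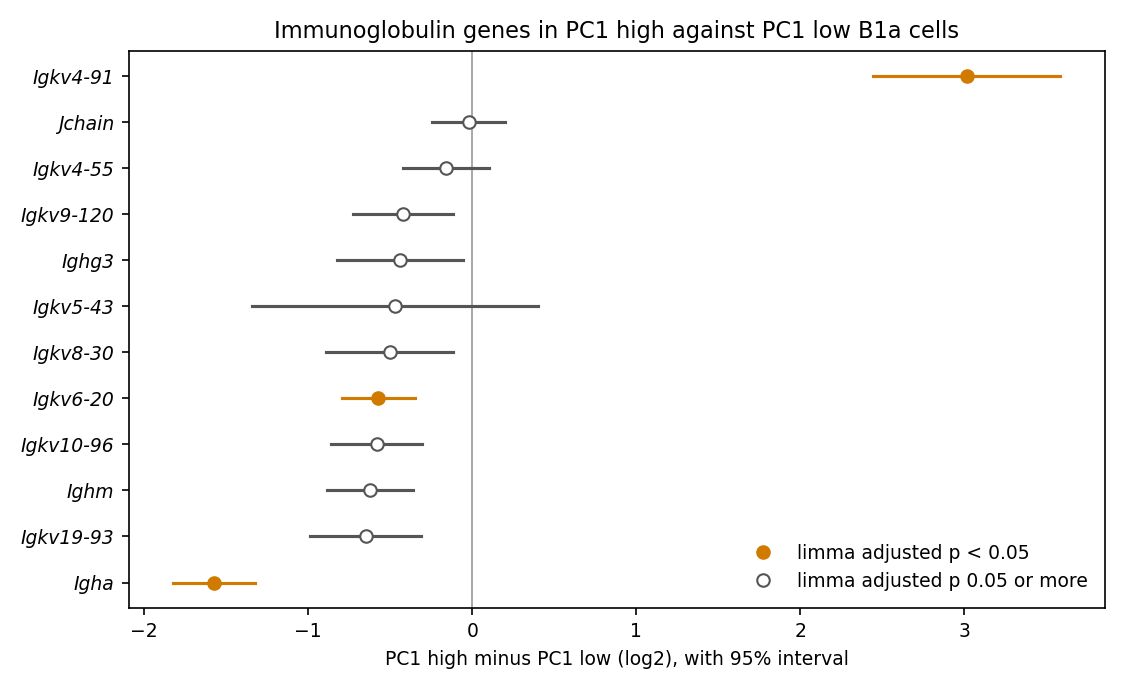
Log2 difference between PC1 high and PC1 low B1a cells for each immunoglobulin constant region gene, Jchain and each light chain variable segment measured by a probe set of its own, with limma's 95% interval (6 arrays per group). Igkv4-91 lies at 3.01 and the other 11 genes lie below 0, from -0.02 for Jchain to -1.57 for Igha.

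Follicular B-2 cell genes shifted down in PC1 high cells. Of 17 measured members, 16 had values below 0 and the median log2 difference was -0.25 (camera adjusted p = 2.21e-16, and 0.00708 with an estimated correlation). Adjusted over all genes 3 were lower and none higher, and adjusted over the list alone 9 were lower. Besides Cr2, Fcrl1 and Fcer2a, these 9 included the homing receptor Ccr7 (-0.34, SE 0.07) and the integrin chain Itga4 (-0.25, SE 0.05). B-1 cell associated genes lay on the other side, with 24 of 30 above 0 and a median of 0.11 (camera adjusted p = 3.63e-06). That shift did not pass with an estimated correlation (adjusted p = 0.0751). Anxa2 was higher over all genes, and Cd300lf (0.88, SE 0.17), the galectin Lgals1 (0.59, SE 0.13) and S100a6 (0.28, SE 0.09) were higher and Apoe (-0.25, SE 0.08) lower when adjusted over the list alone.

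The 19 marginal zone B cell genes did not shift as a group (median -0.03, adjusted p = 0.631). Of them Cr2 was lower over all genes, and adjusted over the list alone the sphingosine-1-phosphate receptor S1pr3 (0.41) and Sox5 (0.22) were higher.

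Transcription factors of B cell identity were lower in camera's preset test (median -0.07, 17 of 20 below 0, adjusted p = 2.30e-05), but not with an estimated correlation (adjusted p = 0.243) or without PC1 high replicate 5 (adjusted p = 0.0591). None passed over all genes; Irf8 (-0.36, SE 0.08), Ets1 (-0.29, SE 0.07) and Mef2c (-0.19, SE 0.06) passed when adjusted over the list alone. B cell receptor signalling genes were called lower (adjusted p = 0.0321) with 15 of 30 members on each side of 0 and a median of 0.00 that changed sign under some settings, and not with an estimated correlation (adjusted p = 0.799). Cr2 (-0.61) was lower over all genes, and the Ras activator Rasgrp3 (-0.61) joined it over the list alone.

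Another 3 lists had small shifts that camera called with its preset correlation and that no single gene carried past the threshold, over all genes or over the list alone. Class switching and somatic hypermutation genes were lower (median -0.08, 11 of 17 below 0, adjusted p = 0.0205), with Prkdc at -0.16 and Bcl6 at -0.28. Regulatory B cell and inhibitory molecules were higher (median 0.05, 20 of 25 above 0, adjusted p = 0.0205), with the ATP-hydrolysing ectoenzyme Entpd1 at 0.22 and Tgfb1 at 0.16. Among the members below 0 was Btla, at -0.19 (SE 0.09). Immediate early genes were higher (median 0.07, 16 of 25 above 0, adjusted p = 0.0393), with Junb at 0.17 and Ier2 at 0.17. Among the members below 0 was Cd69, at -0.59 (SE 0.28). With an estimated correlation the adjusted p values of these lists were 0.0751, 0.0751 and 0.313, in that order.

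**Figure D3:**
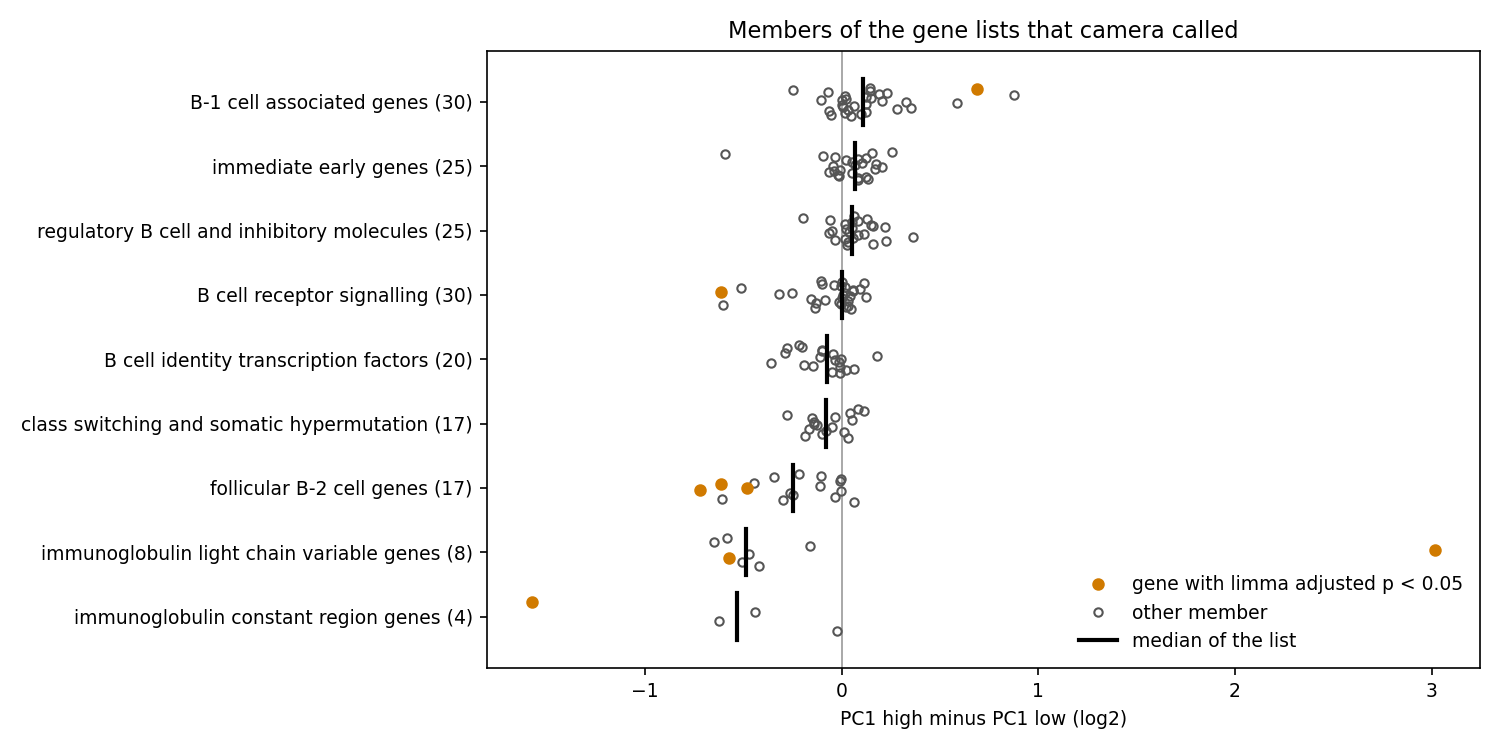
Log2 difference between PC1 high and PC1 low B1a cells for each measured member of the 9 gene lists called by camera with its preset correlation; filled points are genes with a limma adjusted p under 0.05, open points the other members, and black lines the list medians. The number measured stands after each name. The immunoglobulin and follicular B-2 medians lie at -0.25 or lower, and the other 6 within 0.11 of 0.

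Plasma cell differentiation genes had a median of 0.02 (camera adjusted p = 0.123) and went both ways; they were called higher without PC1 high replicate 5 (median 0.06, adjusted p = 0.00461) and with dim genes left out (0.0430). Adjusted over the list alone, Pon3 (0.53), the master regulator Prdm1 (0.48), the elongation factor Ell2 (0.37), Creb3l2 (0.23) and Txndc5 (0.19) were higher, and the surface receptor Slamf7 (-0.63) was lower. Unfolded protein response genes had a median of 0.05 (adjusted p = 0.0708) and were called higher under 7 of 23 alternatives, with an adjusted p of 9.58e-05 without PC1 high replicate 5. MHC class II presentation genes had a median of 0.01 (adjusted p = 0.0708). They were called lower under 5 of 23 alternatives, quantile normalization and array weights among them, each with a median below 0, and the adjusted p was 0.00329 without PC1 high replicate 1. H2-Ob (-0.34) and H2-Eb2 (-0.22) were lower over the list alone.

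No shift was called for the other lists of cell functions. Fetal and early-wave lymphopoiesis genes had a median of 0.02 (adjusted p = 0.347), cell cycle genes 0.02 (0.741), extracellular nucleotide metabolism genes 0.02 (0.505) and chemokine receptor, integrin and homing genes -0.01 (0.754). Within the homing list Ccr7 and Itga4 were lower and Ccr9 (0.45) and S1pr3 were higher over the list alone. Toll-like receptor and innate sensing genes had a median of 0.06 (0.607), NF-kB targets 0.02 (0.961), interferon-stimulated genes 0.03 (0.193) and cell survival genes 0.01 (0.961). Cytokines and their receptors had a median of 0.02 (0.961), with the lymphotoxin chain Ltb (-0.54) lower over the list alone, glycolysis genes 0.01 (0.550) and lipid metabolism genes 0.00 (0.858).

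Marker lists of other cell types were not called either, apart from mesothelial and stromal markers without PC1 high replicate 2 (adjusted p = 0.0268). Over all arrays their medians and camera adjusted p values were -0.01 and 0.690 for T cells, 0.00 and 0.754 for macrophages and monocytes, 0.01 and 0.961 for NK cells, 0.01 and 0.754 for neutrophils, -0.02 and 0.549 for mast cells, 0.00 and 0.882 for dendritic cells, 0.03 and 0.674 for erythroid cells and platelets, and 0.02 and 0.183 for mesothelial and stromal cells. The medians of the T cell and macrophage lists changed sign with quantile normalization. Among their members Krt18 (0.25), a keratin, and Ccr9, also in the homing list, passed over the list alone.

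One array of each group, PC1 high replicate 5 and PC1 low replicate 2, stood apart from the rest in both the spread and the floor of its values. The interquartile range over genes was 1.24 and 1.26 on these arrays and between 1.33 and 1.46 on the other 10. The median of 1194 olfactory and vomeronasal receptor genes was 6.54 and 6.53, against at most 6.38 elsewhere. Without these 2 arrays limma called 13 higher and 6 lower genes, 14 of them among the 25, and the follicular B-2 median was -0.24.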

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

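The counts of splits for the gene calls and for the list calls with the preset correlation were planned; the same count with an estimated correlation, the splits for single lists and the tests of plasma cells, B-2 cells, the 2 arrays that stand apart, compressed signal and swapped labels were chosen after the results were seen.

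Of 100 splits of the 12 arrays into 6 and 6, drawn from 462, only the real grouping called as many as 25 genes. The others called at most 1. Chance is thus unlikely to give so many calls, though the splits do not test any single gene. At an unadjusted p under 0.05 limma gave 444 higher and 516 lower genes of 19938, no more than chance gives at that limit. For the gene lists called with camera's preset correlation, chance can give as many. At least the 9 lists of the real grouping were called by 16 of 100 splits, the real one included, and the highest other called 15. With an estimated correlation the real grouping called 3 lists, 3 of 100 splits, the real one included, called at least as many and the highest other called 4; since this count was chosen after the results were seen, chance is not taken as excluded for the list calls. Taken by itself, each of these 3 lists (follicular B-2, immunoglobulin constant region and light chain variable genes) had its smallest camera p in the real split. Those unadjusted camera p values were 6.91e-18, 1.33e-10 and 5.02e-06, against 2.65e-13, 8.49e-06 and 1.54e-05 at lowest in the other splits. As small a p came in 7 of 100 splits for B-1 genes, 12 for B cell identity and 63 for receptor signalling. It came in 4 for regulatory molecules, 9 for immediate early genes and 10 for class switching, the real split included each time.

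Igha was lower in PC1 high cells in 6 of 6 arrays, and Ighm had the same direction. A candidate explanation is a share of plasma cells in the PC1 low sorts, although a gate on CD19 and CD5 removes many of them. It would raise plasma cell genes in PC1 low cells, but the mean of the 22 listed genes was 0.0488 log2 units higher in PC1 high cells, with a 95% interval from -0.0197 to 0.117, and 10 of the 22 also stand in another list. Of its members Prdm1 was at 0.48 (SE 0.13), which speaks against plasma cells, while Slamf7 at -0.63 (SE 0.15) goes with them. Sdc1 (0.03, SE 0.05) and Tnfrsf17 (0.01, SE 0.07) lay near 0 but were among the dim genes. Jchain (-0.02, SE 0.10) averaged 6.38 and 6.41, level with the olfactory and vomeronasal receptor genes (array medians 6.27 to 6.54). It thus showed no rise in PC1 low cells, but whether its probe set would read plasma cell RNA was not tested. As the list's interval includes 0, a few plasma cells and a difference between B1a cells cannot be told apart. The 2 arrays that stand apart were not the cause, since Igha differed by -1.67 without them (limma adjusted p = 9.82e-05, against 3.10e-06 to 0.000153 over its alternatives). A difference in IgA expression that goes with PC1 stays open as a hypothesis. Whether the probe sets named Igha or Ighm alone read only the constant region was not tested. The difference thus cannot be assigned to IgA rather than to the heavy chain variable segments that other probe sets list with Igha.

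Follicular B-2 genes were lower in PC1 high cells, by a median of -0.25 over 17 genes. Some B-2 cells in the PC1 low sorts are a candidate explanation, although the gate excluded CD23, and a varying share of them would make the listed genes rise and fall together within a group. Over the 10 arrays other than the 2 that stand apart they did, with a mean pairwise correlation of 0.164 that lay at the 99.9 percentile of 1000 random lists matched on expression (median -0.00). Shared regulation of these genes in B1a cells could give the same co-variation, and 10 of the 17 also stand in another list. The shift did not come from the 2 arrays that stand apart, since its median without them was -0.24 (camera adjusted p = 5.34e-14, against 5.04e-18 to 0.00708 over its alternatives).

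PC1 high replicate 5 and PC1 low replicate 2 stood apart on the first principal component, which held 33.2% of the variance, at 27.6 and 19.4. Their deviations from the group means correlated at 0.615, and array weights were 0.330 and 0.389. A compressed signal on these arrays may be the source. Receptor genes that B cells are not known to use read at least 0.151 log2 units higher on both than on any other array. The interquartile range over genes was smaller by at least 0.0755. Both measures had already set these arrays apart above, so they describe such a signal and are not a separate test of it. A swap of their labels is argued against by a score over the 19 genes called from the other 10 arrays, on which PC1 high replicate 5 (0.133) lay 0.543 above PC1 low replicate 2 (-0.410), each on its own group's side; the other arrays scored 0.446 to 0.639 in PC1 high and -0.628 to -0.349 in PC1 low. No biological explanation was tested, since the labels give none.

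Each of 58 sets of 6 values was tested for an array whose gap to the nearest other array took up an unusual share of the group's range; 6 met the limit, and chance gives about 1 in 20. In PC1 low replicate 2 the interquartile range (1.26, against 1.35 to 1.41 on the other PC1 low arrays) had a gap share of 0.630, and the receptor gene median (6.53, against 6.29 to 6.34) one of 0.808. Ifi207 in PC1 high replicate 5 read 8.41 against 9.85 to 10.16 elsewhere in the group, a gap share of 0.822. Etl4 in PC1 low replicate 6 read 8.48 against 8.22 to 8.25, a gap share of 0.862. Tsga10 in PC1 high replicate 1 read 7.46 against 7.12 to 7.24, a gap share of 0.648. Cd5 in PC1 low replicate 1 read 8.39 against 8.50 to 8.56, a gap share of 0.642.

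Outside the gene-level comparison, 8 of the 12147 probe sets without a listed gene differed between the groups when every probe set of the table was tested with limma, and all 8 were lower in PC1 high cells.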

How the results depend on the processing

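Leaving out the 2 arrays that stand apart, the Xist covariate and the fit over every probe set were chosen after the results were seen; the other settings were planned. No called gene changed sign and no called list changed camera's direction, but the receptor signalling median went above 0 under some settings (0.01 without PC1 high replicate 3 or PC1 low replicate 1). Over the gene-level settings the 25 called genes kept their call and sign in 427 of 544 checks, lost the call in 117 and changed sign in 0. Of them 9 kept the call in each of these checks (Igkv4-91, Ifi207, Ahnak2, Anxa5, Etl4, Eps8, Igha, Cr2 and Fcer2a), though Cr2 lost it in the fit over every probe set, and the highest adjusted p of the others was 0.177, for Igkv6-20. Fcer2a was itself among the dim genes, so it was not tested in the setting that left them out. Against 16 higher and 9 lower genes, limma called 17 and 14 with every annotated probe set tested by itself, 49 and 32 with array weights, 8 and 5 with centred arrays, 19 and 14 with quantile normalization, and 7 and 15 over every probe set of the table. Array centring kept 13 of the 25 and quantile normalization 23, and neither moved the median of all genes by more than 0.1; the cause was not tested. An adjusted p under 0.01 left 4 and 2, and at least a 2-fold difference 4 and 1, by construction. With the replicate block there were 23 and 16, 21 of the 25 among them and Sft2d2, Tsga10, Igkv6-20 and E030011O05Rik not, and the only list call that changed was that of the unfolded protein response, gained just under the threshold. Deviations of equal numbers correlated between -0.48 and 0.19, over 0.1 in 3 of 6, and 1 of 6 PC1 high arrays matched its own number best. The -0.48 was that of number 2, and numbers 2 and 5 each hold an array that stands apart. Deviations shared by those arrays can hide a shared mouse, so these correlations cannot decide whether equal numbers pair. The Xist level was high on 3 arrays of each group, and the Y-linked genes Kdm5d, Eif2s3y and Uty were high on the other arrays. By these genes each group held preparations of both sexes, and sex was not in the main model. The Xist level fell in the same class in 6 of 6 pairs, which random pairing gives with a probability of 0.05. Leaving out single arrays gave 7 to 30 higher and 6 to 12 lower genes. Higher genes numbered 7 without PC1 high replicate 3 or PC1 low replicate 1, which kept 12 of the 25 each, 10 without PC1 high replicate 2 and 30 without PC1 high replicate 5. The 9 list calls became 3 with an estimated correlation and 2 with fry, and leaving out single arrays gave 7 to 10. The follicular B-2 and constant region lists were called under every setting in which they were tested. The B cell identity list lost its call without PC1 high replicate 5 (adjusted p = 0.0591), the regulatory list without PC1 high replicate 1 (0.242) or PC1 low replicate 2 (0.128) or 5 (0.0658), and the class switching list without PC1 high replicate 5 (0.124) or 6 (0.0649) or PC1 low replicate 3 (0.0633) or 4 (0.0612). The immediate early list lost it without any of 6 arrays (up to 0.191, PC1 high replicates 1, 2 and 4 and PC1 low replicates 2, 3 and 4), as did the receptor signalling list (up to 0.844, PC1 high replicates 3, 4 and 5 and PC1 low replicates 1, 4 and 6). Dim genes left out also ended the class switching and receptor signalling calls (both 0.0935), centring those of receptor signalling (0.0523) and immediate early genes (0.0806), array weights that of immediate early genes (0.143), and leaving out the 2 arrays that stand apart those of receptor signalling (0.154) and immediate early genes (0.0611). Lists that were not called gained a call in 15 of 526 checks, 7 of them of the unfolded protein response, 5 of MHC class II, 2 of plasma cell genes and 1 of mesothelial markers. The Enpp1 difference gave no value, and a robust prior was not run for lists. The table gives no detection values, so signal over background was not known per gene.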

Other observations

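The genes in the first part below were chosen after the results were seen, from an alternative that was planned; the test of the Igkv4-91 hypothesis was chosen after the result was seen.

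With arrays weighted by their quality, 56 further genes passed limma's threshold that had not passed with equal weights, 33 higher and 23 lower in PC1 high cells (n = 6 per group). Among the lower ones were Trps1, a transcriptional repressor (weighted log2 difference -1.27, SE 0.23), Kmo, the kynurenine hydroxylase (-0.78, SE 0.16), the lymphocyte receptor Slamf6 (-0.67, SE 0.13), Ighm (-0.65, SE 0.13), the kinase Jak2 (-0.42, SE 0.07) and the class II antigen presentation regulator H2-Ob (-0.33, SE 0.06). The B cell transcription factors Irf8 (-0.41) and Ets1 (-0.30) and the homing molecules Ccr7 (-0.38) and Itga4 (-0.24) also passed. Their adjusted p values ranged from 0.00579, for the trafficking adaptor Gga2, to just under the threshold.

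Higher with array weights were the inhibitory receptor Cd300lf (0.84, SE 0.15), Eaf2, a partner of elongation factors (0.70, SE 0.13), and the receptor Slamf9 (0.55, SE 0.11). So were the transcription factors Nfil3 (0.52, SE 0.09) and Ets2 (0.44, SE 0.09) and the autophagy receptor Sqstm1 (0.46, SE 0.08). The sphingosine-1-phosphate receptor S1pr3 (0.46, SE 0.08) and Igf2r, the mannose-6-phosphate receptor (0.38, SE 0.06), were higher too. Ifi205, of the same family as Ifi207, also passed (0.42, SE 0.08). It averaged 5.01 in PC1 high and 4.59 in PC1 low cells, below the olfactory and vomeronasal receptor medians of 6.27 to 6.54. The sialyltransferases St3gal4 (0.55, SE 0.10) and St3gal6 (-0.61, SE 0.10) went in opposite directions.

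A larger share of cells carrying Igkv4-91 in PC1 high sorts may account for its 8.08-fold difference, since each B cell uses mostly a single light chain and the other segments would then be lower. As that predicts, 7 of the other 7 kappa segments named alone had values below 0, of which 5 passed over the list alone. Among those 5, Igkv8-30 read near the floor and a second probe set of Igkv19-93 gave -0.08. But Ighm was at -0.63 (SE 0.12) as well, which this hypothesis does not predict if its probe set reads only the constant region. That was not tested, and other probe sets of Ighm gave -0.37 and -1.19. Lower immunoglobulin RNA in PC1 high cells as a whole would lower the other segments too, but it would not raise Igkv4-91. Whether more cells carry Igkv4-91 or the same cells hold more of its RNA stays open, and protein or single-cell data were not analysed here.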
